A study of Drosophila melanogaster with 2 samples.

How the data were processed

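Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos of both sexes, collected 0 to 24 h after egg laying. The fly line carries a transgene from which CG34376 is made with a green fluorescent protein fused to its C terminus. Per the labels, the 2 libraries are biological replicates 2 and 3 of the same experiment, chromatin was sheared by sonication and fragments of 200 to 800 bp were taken. The labels conflict on 1 point. A free-text line calls each library an input control, whereas the assay title is transcription factor ChIP-seq, the antibody field names CG34376 and a separate control experiment is listed. The libraries were treated here as immunoprecipitated samples. They form 1 group, so no comparison between groups was possible.

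The authors deposited a list of candidate peaks for each replicate, a list for the pooled replicates, and a thresholded list, on build dm6. Per the labels' file listings, both replicates were set against the same control file, and the thresholded list is the optimal set after an irreproducible discovery rate (IDR) procedure. The aligner, the peak caller and their versions are not given in the sources used here. Each deposited line holds an interval, a signal value in the authors' own units, a −log10 q value and the offset of the summit. The deposited signal was used to rank, filter and describe peaks within a list, and its correlation between replicates was by rank. The 3 candidate lists hold 30000 lines each, which is a preset length and not a count of binding sites. The 7025 thresholded lines are exactly the 7025 lines of the pooled list with the highest signal. Each line was counted as 1 peak: 193 thresholded lines repeat the interval of another line with a different summit, and merging overlapping intervals gave 6272 regions. The summit offset pointed past the end of the interval in 2 thresholded lines and was set to its last base. Read counts per library are not used here, so the depth is unknown and confidence intervals cover counting of peaks or genes only.

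Peaks were annotated with Ensembl release 115 (BDGP6.54) and the sequence of Release 6 of the fly genome, which is build dm6. No interval reached past the end of its chromosome arm, and 17681 of the 17683 genes used had the same start and end in the RefSeq annotation of that assembly. The 17683 genes have 23517 distinct transcription starts on the arms 2L, 2R, 3L, 3R, 4 and X, the only ones in the lists. A summit was called promoter within 500 bp of any start. Other summits were called 5' UTR, coding exon, 3' UTR, intron or intergenic, in this order of precedence. The intron class holds every position inside a gene outside UTRs and coding exons, and so includes exons of noncoding genes. A gene was called bound when a thresholded summit lay within 500 bp of any of its starts, so that 1 peak can count for several genes.

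Thresholded peaks were compared with the 20248 pooled candidates that overlap no thresholded peak. For each replicate, the 7025 candidates with the highest signal were analysed in the same way, which gives a mean and SD over n = 2. Replicates were compared by the share of these candidates that overlap by at least 1 bp, beside 100 placements shuffled within chromosome arms, and by Spearman's rho of the signal at thresholded peaks, with an interval from 1000 bootstrap samples of peaks. Shares were tested with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05. The families were 6 feature classes, 6 arms, 29 gene lists, 32 motifs and 2080 6-mers. Of 31 gene lists, 2 had fewer than 5 genes in the background and were not tested: chorion and vitelline membrane genes, with 1 of 2 bound, and male germline genes, with 0 of 1 bound. The background of the gene lists was the 9570 genes with a pooled candidate summit within 500 bp of a start. A few listed symbols had no match in the annotation and are not analysed here. Motifs and 6-mers were counted on both strands in windows of 100 bp on each side of the summit, against windows of equal length centred 600 bp to its left and right. These p-values are over peaks, genes or windows and not over replicates; neighbouring peaks and genes are not independent. Intervals of shares are 95% Wilson intervals, and intervals of odds ratios are 95% intervals from the log odds ratio.

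The tests, lists, motifs, most alternative settings and the rule for named genes were fixed before the data were examined. The rule names CG34376; the gene of the nearest start for the 20 thresholded peaks of highest signal whose summit lies within 100 bp of a summit among the 7025 highest of both replicates; the 3 members with the highest promoter signal of each list past the threshold, or at most 2 for a list bound less often; and the 10 6-mers with the largest odds ratio among those past the threshold and in at least 5% of peaks. A gene that the rule names is not reported here. Alternatives covered the threshold, leaving out either replicate, the promoter distance, the background, the window and the overlap that counts as shared. The gene list test was tested on simulated data in 100 runs over 9570 genes, each drawn independently. The list of mitochondrial ribosomal protein genes, 69 in the background, was planted with 80% of its genes bound. It was called in 100% of runs, and 0.214% of 2800 tests of other lists were called. No shorter list was planted, so the 100% does not apply to the short lists. In simulated windows, 1 run with the CREB site planted in 5% of them, the planted motif and both planted 6-mers were called. So were 3.23% of 31 other motifs and 0.0962% of 2078 other 6-mers. A single run gives no rate of calls, and no rarer site was planted, so the result does not apply to rare motifs. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.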

Results

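Binding of a green fluorescent protein fusion of CG34376, an annotated gene on 3R, was profiled by ChIP-seq in whole embryos aged 0 to 24 h. The data are peak lists from 2 libraries of 1 group, biological replicates 2 and 3, with 30000 candidate peaks each, a pooled list of the same length and 7025 thresholded peaks. Thresholded peaks covered 2.69 Mb, and their signal ranged from 163 to 3316 with a median of 252, in the authors' units.

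The first question was whether the replicates placed and ranked peaks alike. The strongest site of both replicates was the same intron of CG11050 on 2L, and the promoter of Ugalt, which encodes a transporter of UDP-galactose, had rank 2 in both. Of the 7025 highest candidates of replicate 2, 84.9% were overlapped by the 7025 highest of replicate 3, and 84.0% in the other direction. The mean of both shares, 84.4%, lay above all 100 shuffled placements, which averaged 4.15% and reached at most 5.05% (permutation p = 0.0099, the smallest that 100 shuffles can give). The shuffles spread intervals evenly along an arm, so this p-value shows only more overlap than even placement. With the 7025 lowest candidates of replicate 3 as partner, the share, 6.26%, also lay above its shuffles, which averaged 4.39%. Of the thresholded peaks, 5896 (83.9%) overlapped the 7025 highest candidates of both replicates and 32 (0.456%) those of neither. The thresholded peaks were selected from the pool of these same replicates, so these shares and the correlation at these peaks are not an independent test of reproducibility. Across the 7000 thresholded peaks found in both candidate lists, Spearman's rho of the signal was 0.699 (95% bootstrap interval 0.685 to 0.714). This correlation is across peaks, which are not independent replicates, and both replicates shared a control.

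**Figure D1:**
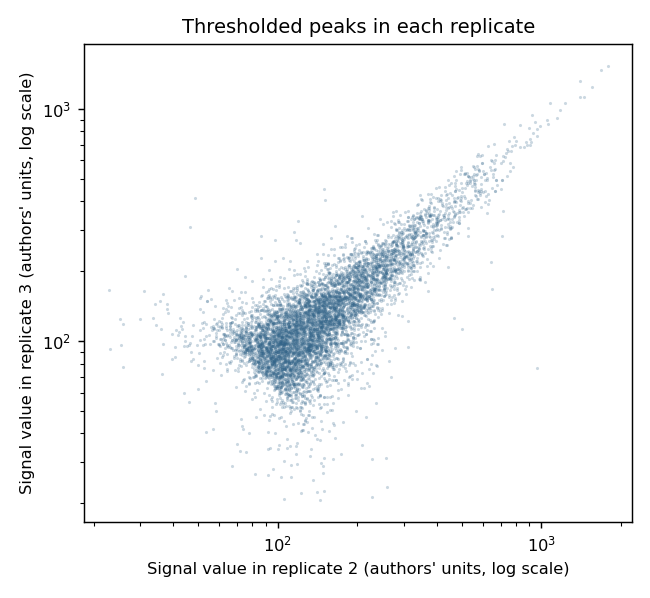
Each point is 1 of 7000 thresholded peaks, with its signal value in replicate 2 on the x axis and in replicate 3 on the y axis (authors' units, log scales). Spearman's rho is 0.699, and the points spread more widely at low signal than at high signal.

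The tagged gene was examined first. CG34376 (FBgn0085405) spans 22448099 to 22460749 on the plus strand of 3R, and its own promoter carried a strong peak. The summit of that peak, at 22448078, lay 21 bp upstream of the single annotated start, with a signal of 1355, rank 40 of the thresholded list, rank 59 in replicate 2 and rank 28 in replicate 3. A further 5 summits lay in the gene, all in introns, at 22450269, 22453464, 22454553, 22455459 and 22456193, with signals from 430 to 928. With 20 kb added on each side the region held 10 thresholded summits. The other 4 of these lay at the promoters of CG34288, CG7054 (2 summits) and Nrx-1, which encodes a neurexin, a synaptic adhesion protein. The weaker CG7054 summit, with a signal of 314, had only rank 18787 in replicate 2 and rank 7743 in replicate 3. Among 1000 windows of the same length around other protein-coding genes, the median was 4 summits, the 95th percentile 12 and 90.1% held fewer than 10, so that 99 windows held at least as many. Counting each gene with 500 bp on each side, CG34376 had 6 thresholded summits, and 145 other genes of 13945 had as many or more. The share of windows with fewer summits was 92.2% with replicate 2 alone and 85.9% with replicate 3 alone.

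**Figure D2:**
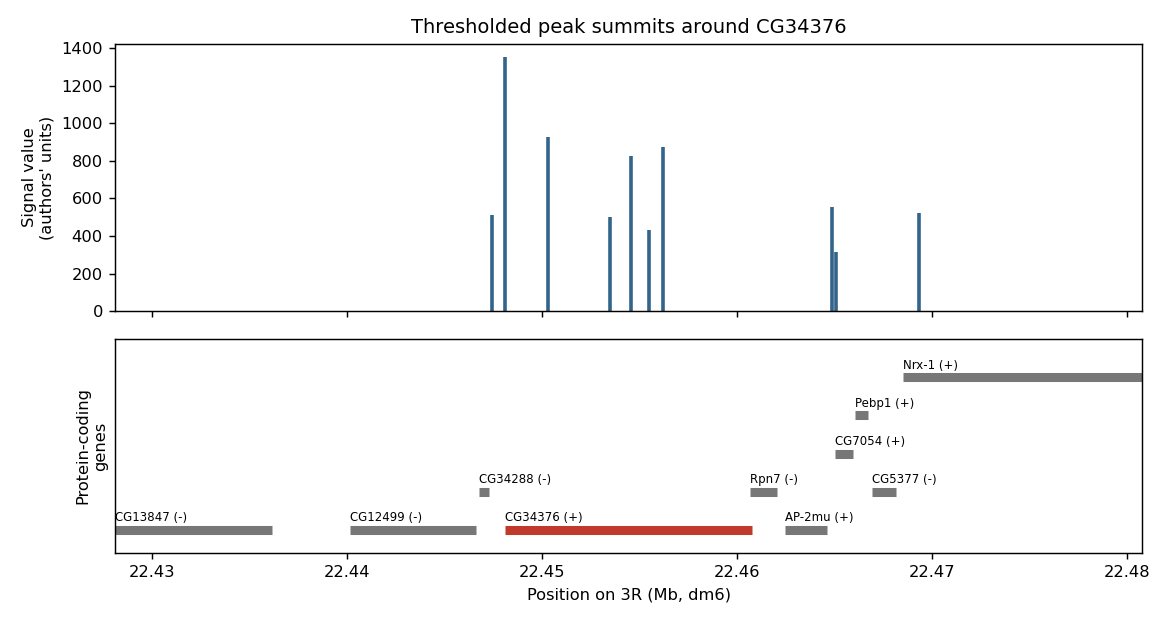
Signal value (y axis, authors' units) of the 10 thresholded summits within 20 kb of CG34376 against position on 3R (Mb), above the protein-coding genes with their strands. The highest bar, 1355, stands at the start of CG34376 (red), and 5 others lie inside the gene.

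The strongest peaks lay in an intron of CG11050 and at the promoters of Ugalt, Gapdh2 and CG14100. The 20 peaks named by the fixed rule were ranks 1 to 20 of the pooled list, so that every one met the condition in both replicates. Of these, 12 were at promoters, 6 in introns and 2 intergenic, and in 16 the summit lay upstream of the nearest start. The strongest (signal 3316) covered 6612294 to 6613011 on 2L, in an intron 1019 bp downstream of a start of CG11050 (FBgn0031836). The Ugalt peak (FBgn0024994; signal 3150) covered 2703661 to 2704105 on X, with its summit 49 bp upstream of the start. The peak at Gapdh2 (FBgn0001092), a glyceraldehyde-3-phosphate dehydrogenase of glycolysis, covered 15867716 to 15868328 on X with a signal of 2799, and its summit lay 163 bp upstream of the start. A second glycolytic gene, Hex-A, which encodes a hexokinase, had a promoter peak with a signal of 1726. The promoter peak of CG14100 had a signal of 2720. Genes of transcription factors in the set were cbt (intron, 2569), Trl, which encodes GAGA factor (intron, 2283), and Sox14 (promoter, 1830). The promoter of Hsp83, a major chaperone gene, had a signal of 2185, and that of mRpL41, a protein of the mitochondrial ribosome, 2149, within 500 bp of a start of lncRNA:CR44463 as well. Further promoter peaks lay at Pal1, CG11309, amon, which encodes a prohormone convertase, px and Art3, with signals from 1683 to 2065. Those at Pal1, CG11309 and Art3 also lay within 500 bp of a start of Pdrg1, CG7632 and mRpS10, respectively. The remaining peaks lay in introns nearest to lncRNA:CR44619 (2550), CG9663 (1938) and Lk6, which encodes a protein kinase (1869), and between genes nearest to jp, a junctophilin (1864), and DNAlig3 (1805). The nearest start does not show which gene a distal peak acts on.

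Thresholded peaks lay mainly at promoters. Of 7025 summits, 4302 (61.2%, 95% Wilson interval 60.1 to 62.4) were within 500 bp of a transcription start, against 32.5% (31.8 to 33.1) of the 20248 remaining candidates, an odds ratio of 3.29 (3.11 to 3.48). Fisher's exact p was too small for double precision arithmetic. The promoter share of the highest candidates was 60.9% ± 0.805 (SD, n = 2 replicates) and that of the remaining candidates of each replicate 32.05% ± 1.15 (SD, n = 2), a difference many times the spread between replicates. Promoter summits lay slightly upstream, with a median of -37 bp from the nearest start and 61.4% on the upstream side, and 31.7% of all thresholded summits were within 100 bp of a start. Against shuffled positions, of which 13.8% were at promoters, the odds ratio was 9.88.

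Introns held 2048 thresholded summits (29.2% against 45.1% of the remaining candidates, odds ratio 0.501, adjusted p = 3.57e-124, Fisher's exact test). Intergenic sequence held 466 (6.63% against 14.5%, odds ratio 0.420, adjusted p = 3.83e-73, Fisher's exact test). Coding exons held 34 (0.484% against 3.63%, odds ratio 0.129, adjusted p = 2.67e-57) and 3' UTRs 117 (1.67% against 3.26%, odds ratio 0.503, adjusted p = 5.08e-13), by the same exact test. Against shuffled positions the odds ratio was 0.0306 for coding exons and 0.188 for intergenic sequence. The share in 5' UTRs beyond 500 bp from a start was 0.826% against 1.08% and did not pass the threshold of Fisher's exact test (adjusted p = 0.0722), though it did with replicate 2 alone (adjusted p = 0.0326) and in the 1000 strongest peaks (adjusted p = 0.0370). In the highest candidates of each replicate the intron share was 29.4% ± 0.926 and the intergenic share 6.70% ± 0.0302 (SD, n = 2).

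**Figure D3:**
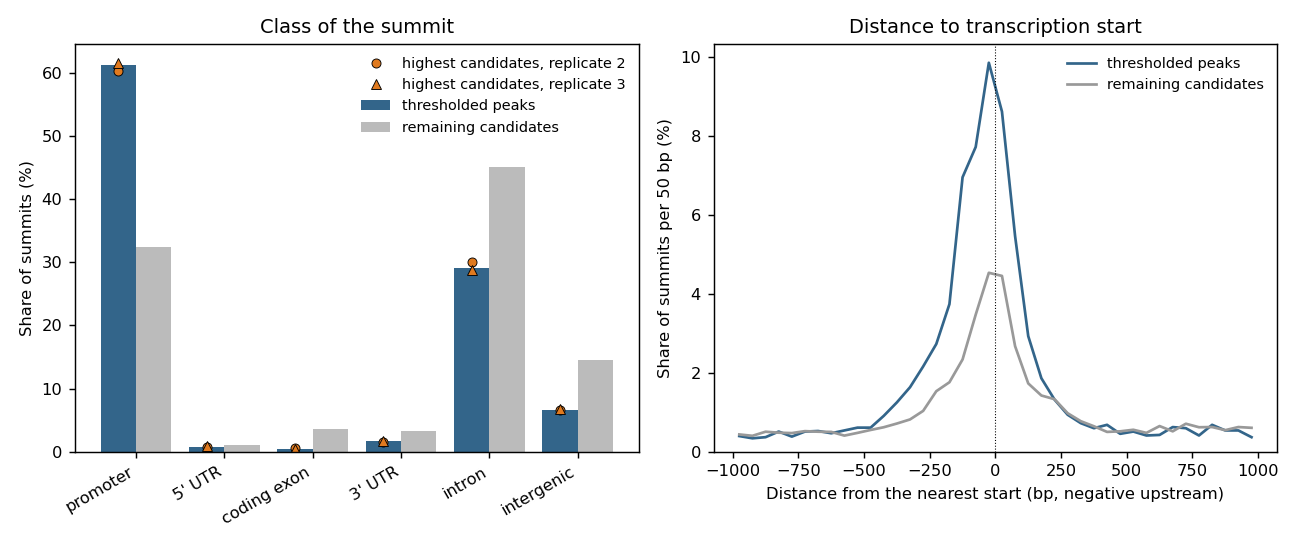
Left, share of summits (%) in each class for thresholded peaks (blue), remaining candidates (grey) and the 7025 highest candidates of each replicate (markers). Right, share of summits per 50 bp against distance from the nearest start (bp, negative upstream); thresholded peaks form a higher maximum just upstream of the start than the remaining candidates.

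By chromosome arm, 2R held more of the thresholded peaks and X fewer than of the remaining candidates. Arm 2R had 1483 peaks (21.1% against 18.3%, odds ratio 1.19, adjusted p = 9.3e-07) and X had 1103 (15.7% against 18.8%, odds ratio 0.803, adjusted p = 1.83e-08, Fisher's exact tests). The density was 58.6 peaks per Mb on 2R, 54.8 on 2L, 52.0 on 3R, 51.4 on 3L, 46.9 on X and 28.2 on chromosome 4. The shares in the highest candidates of each replicate were 21.0% ± 0.413 for 2R and 15.7% ± 0.161 for X (SD, n = 2). Chromosome 4, a small and largely heterochromatic chromosome, had 38 peaks (odds ratio 0.679, adjusted p = 0.0681, Fisher's exact test), and the call depended on the library, with adjusted p = 0.00104 for replicate 2 alone and 0.522 for replicate 3 alone. Against the lengths of the arms it passed (odds ratio 0.535).

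Genes of the cytosolic ribosome were bound more often than other genes. Of 86 cytosolic ribosomal protein genes in the background, 80 (93.0%, Wilson interval 85.6 to 96.8) had a thresholded summit within 500 bp of a start, against 4615 of all 9570 background genes (48.2%), an odds ratio of 14.6 (adjusted p = 9.94e-18, Fisher's exact test). The share was 91.3% ± 0.747 in the separate replicates, against 47.5% ± 1.08 of all background genes (SD, n = 2). The median promoter signal of bound members was 526, against 268 for all bound genes. Both strongest members were on 3R, RpS27 (FBgn0039300; peak 25247230 to 25247746, signal 1581) and RpL32 (FBgn0002626; peak 30045940 to 30046602, signal 1214.5), with summits 12 bp downstream and 30 bp upstream of their starts. The 6 members without a bound promoter, named after their values were seen, were RpL15, RpL5, RpL24-like, RpS10a, RpS15Ab and RpS5b.

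Genes of transfer RNAs were bound less often: 72 of 199 (36.2%, Wilson interval 29.8 to 43.1; odds ratio 0.602, adjusted p = 0.0082, Fisher's exact test), or 36.6% ± 1.53 in the separate replicates (SD, n = 2). The strongest bound members were tRNA:Tyr-GTA-1-8 (FBgn0012024; peak 8669166 to 8669689 on 3R, signal 1045) and tRNA:Leu-CAA-2-1 (FBgn0011909; 13430847 to 13431348 on 2R, signal 886), whose peak lay closer to the start of tRNA:Ile-AAT-1-4. By the same exact test, the call did not hold with replicate 2 alone (odds ratio 0.682, adjusted p = 0.163), within 200 bp of a start (0.621, adjusted p = 0.0694), in the 3512 peaks with the higher signal (0.705, adjusted p = 0.301), in the 1000 strongest peaks (0.389, adjusted p = 0.0903), or against all annotated genes (0.913, adjusted p = 0.618). Nor did it hold against random lists matched on the number of starts (odds ratio 0.765, permutation, adjusted p = 0.419), and over all alternatives adjusted p ranged from 0.000301 to 0.618. Transfer RNA genes lie in clusters in which 1 peak can count for several genes. The low share was not particular to them. Of 822 background genes annotated as ncRNA 36.1% were bound, against 49.7% of 8426 protein-coding genes, while snoRNA and snRNA genes had 47.9% and 53.8%.

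The other 27 lists did not pass the threshold in the comparison fixed before the data were examined. None of the 7 Hox genes in the background had a bound promoter (0%, Wilson interval up to 35.4%, adjusted p = 0.116, Fisher's exact test), and cuticle protein genes had 2 of 14 (odds ratio 0.179, adjusted p = 0.116). Cuticle protein genes did pass, as less often bound, in 5 alternatives: replicate 3 alone (adjusted p = 0.0238, Fisher's exact test), within 1000 bp of a start (0.00161), any base of the peak (0.0314), nearest starts only (0.0132) and all annotated genes (2.8e-09). Translation factor genes had 26 of 39 bound (66.7%, adjusted p = 0.14), microRNA genes 23 of 65 (35.4%, adjusted p = 0.221) and heat shock genes 7 of 9 (adjusted p = 0.408), all by Fisher's exact test. MicroRNA genes passed, as less often bound, within 1000 bp (adjusted p = 0.00877, Fisher's exact test), with any base of the peak (0.0129), with nearest starts only (0.0159) and against all annotated genes (2.27e-11). Translation factor and trithorax group genes passed as more often bound, and Hox genes as less often bound, within 1000 bp. Against all annotated genes, translation factor, trithorax group, insulator protein and mitochondrial ribosomal protein genes passed as more often bound, and genes of small nuclear and nucleolar RNAs and of odorant and gustatory receptors as less often bound. With nearest starts only, translation factor genes passed as more often and mitochondrial ribosomal protein genes as less often bound, and hemocyte genes passed as more often bound in the 1000 strongest peaks. Mitochondrial ribosomal protein genes had 36 of 69 bound (52.2%), proteasome genes 13 of 33 and genes of small nuclear and nucleolar RNAs 41 of 86. Among regulators of chromatin, 9 of 14 insulator protein genes, 7 of 11 trithorax group genes and 8 of 13 Polycomb group genes were bound. Among signalling genes, 7 of 10 in the EGFR and JAK-STAT list, 4 of 10 in the Notch list and 6 of 10 ecdysone response genes were bound. Embryonic patterning lists gave 2 of 6 maternal and gap genes, 1 of 5 pair-rule genes, 5 of 13 segment polarity genes and 5 of 8 dorsoventral genes. Tissue lists gave 4 of 5 for endoderm and gut, 5 of 7 for hemocytes, 4 of 6 for trachea and epidermis, 6 of 11 for muscle and mesoderm, 2 of 8 neural genes and 2 of 6 germline genes. Cell cycle genes had 7 of 18, circadian genes 4 of 7 and odorant and gustatory receptor genes 2 of 7. Many of these lists are too short for moderate differences to be detectable.

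**Figure D4:**
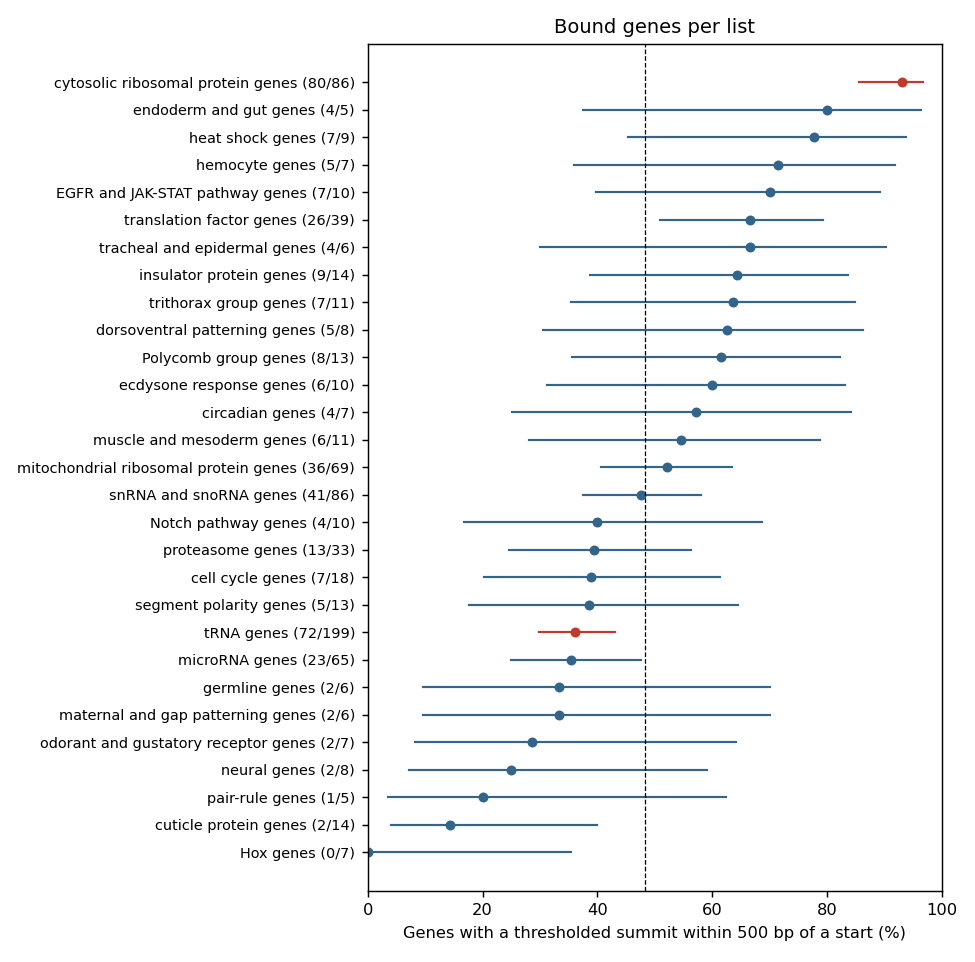
Share of background genes (%) with a thresholded summit within 500 bp of a start, for each of 29 lists, with 95% Wilson intervals and counts in brackets. Red marks adjusted p under 0.05, the dashed line is the 48.2% of all background genes, and cytosolic ribosomal protein genes lie highest at 93.0%.

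Among 6-mers present in at least 5% of peaks, CTTATC, whose reverse complement GATAAG holds a GATA core, had the largest odds ratio. It was within 100 bp of 25.4% of summits against 11.1% of flanking windows (odds ratio 2.74, adjusted p = 1.74e-147, Fisher's exact test). The separate replicates gave 25.2% ± 0.302 of summits and 11.1% ± 0.0403 of flanks (SD, n = 2). Of the 10 named 6-mers, 8 hold GATA on 1 strand: CTTATC, CGATAG (odds ratio 2.60), CGATAA (2.41), GCGATA (2.41), CTGATA (2.40), TGATAA (2.16), GATAAC (2.09) and CCGATA (1.95). These 8 overlap one another and are not separate findings. In CGATAG, CGATAA, GCGATA and CCGATA a C precedes GATA, so they do not match the fixed GATA motif WGATAR. They share CGATA with the fixed DRE motif, TATCGATA. In peaks over 500 bp from a start the odds ratio was 1.79 for CGATAG and 3.46 for CTTATC. It was 2.28 for CGATAA, 2.48 for GCGATA and 1.91 for CCGATA. The other named 6-mers were AGAGAG (2.01), part of a GAGA repeat, and ACACTG (1.95). In all, 497 6-mers were more frequent at summits and 560 less frequent. Mean GC content was 41.8% in summit windows and 42.2% in flanks.

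Among the 32 fixed motifs, 17 were more frequent at summits and 8 less frequent. The GATA site WGATAR was in 47.7% of summit windows against 32.8% of flanks (odds ratio 1.86, adjusted p = 1.4e-94, Fisher's exact test), or 47.5% ± 0.976 against 33.1% ± 0.317 in the separate replicates (SD, n = 2). The DRE, a core promoter element bound by DREF, was in 3.32% against 0.712% (odds ratio 4.79, adjusted p = 8.22e-42), and Motif 1, another such element, bound by M1BP, in 1.30% against 0.178% (odds ratio 7.36, adjusted p = 1.35e-22), by the same exact test. With replicate 2 alone and replicate 3 alone the odds ratios were 3.68 and 5.03 for the DRE and 4.89 and 6.61 for Motif 1. In the 3512 peaks with the higher signal that of Motif 1 was 5.03. Other core promoter elements had smaller odds ratios, 2.41 for Ohler motif 6 (2.36 and 3.62 with replicate 2 or 3 alone), 1.35 for the initiator, 1.45 for the DPE and 1.21 for the TATA box. None of these 4 passed in the distal peaks or in the 1000 strongest peaks, and the TATA box did not pass with replicate 2 alone (odds ratio 1.14, adjusted p = 0.127, Fisher's exact test). Against candidates of the same GC content, Ohler motif 6 (1.503) and the TATA box (1.14) did not pass, nor did the TATA box within 50 bp (1.18) or the DPE in the 3512 peaks with the higher signal (1.48). The GAGA element, bound by the product of Trl, was in 7.64% against 3.42% (odds ratio 2.33, adjusted p = 5.8e-38, Fisher's exact test). Forkhead (odds ratio 1.69), CTCF core (2.30), CA repeat (1.54) and Zeste (1.42) sites were also more frequent. The Zelda site (odds ratio 0.620), the Snail E-box (0.714) and the Bicoid site (0.787) were less frequent, while the Twist E-box did not pass the threshold (odds ratio 0.958, adjusted p = 0.498, Fisher's exact test). The Zelda site did not pass in the 3512 peaks with the higher signal (0.664), within 50 bp (0.775) or in the distal peaks (0.767). Nor did the Snail E-box pass in the distal peaks (0.927), or the Bicoid site within 50 bp (0.838). In the 2723 peaks over 500 bp from any start, the GATA site had an odds ratio of 2.61 and the GAGA element 2.09, while the DRE (0.624, adjusted p = 0.439) and Motif 1 (0.333, adjusted p = 0.591) did not pass Fisher's exact test. Against remaining candidates of the same GC content, the odds ratio was 1.66 for the DRE, 1.52 for the GAGA element, 1.41 for Motif 1 (adjusted p = 0.1, Fisher's exact test), 1 for the CTCF core, 1.03 for the CA repeat, 1.07 for the Zelda site, 0.971 for the Snail E-box and 0.984 for the Bicoid site, and only those of the DRE and the GAGA element among these passed. In the 1000 strongest peaks, with fewer windows, Motif 1 (odds ratio 2.01), the CTCF core (1.38) and the CA repeat (1.07) did not pass, nor did the Zelda (0.640), Snail (0.740) and Bicoid (0.699) sites, whose odds ratios stayed close to those in all peaks.

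**Figure D5:**
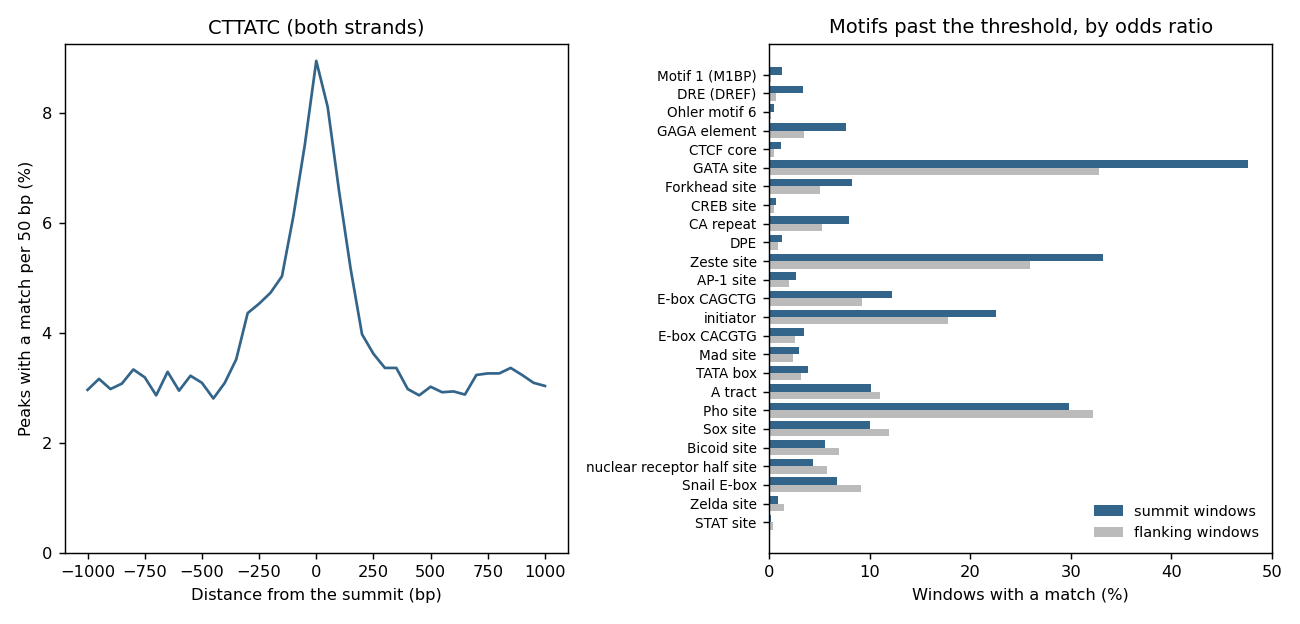
Left, share of the 7025 thresholded peaks (%) with CTTATC on either strand in each 50 bp against distance from the summit (bp), which is highest at the summit, 8.94%. Right, share of windows (%) with each of the 25 motifs past the threshold, at summits (blue) and in flanks (grey), ordered by odds ratio.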

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

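The N lowest candidates as partner, the nearest-start assignment, single replicates for arms, 6-mers and the CG34376 locus, distal 6-mers and merged regions were chosen after seeing the data. The depth of the libraries is unknown, so its effect was not tested, and no paired analysis was possible because there is only 1 group. The promoter odds ratio stayed past the threshold under every setting run, from 3.09 within 200 bp of a start to 9.88 against shuffled positions, and restricting the arms to 2L, 2R, 3L, 3R, 4 and X removed nothing. Replicate overlap lay above its shuffles in each setting run, from 70.8% with reciprocal overlap to 85.3% with 14050 candidates; with the 7025 lowest candidates of replicate 3 it was 6.26%, against 4.39% shuffled. The rank correlation of the replicates' signal was 0.717 in the 3506 peaks with the higher signal. Unless a value shows it, the cause of the changes below was not tested.

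Of 29 gene lists, 2 passed (1 more often, 1 less often bound). The number was 1 (1 and 0) in the 3512 peaks with the higher signal, within 200 bp and against start-matched random lists; 2 (2 and 0) in the 1000 strongest peaks; 4 (1 and 3) with any base of the peak; 7 (3 and 4) within 1000 bp; 9 (5 and 4) against all annotated genes; 6 (2 and 4) with nearest starts only; and 1 to 3 (less often 0 to 2) without either replicate. Cytosolic ribosomal protein genes passed in each, with odds ratios from 11.4 to 19.2. Mitochondrial ribosomal protein genes reversed with nearest starts only (odds ratio 0.330, adjusted p = 0.0132 by Fisher's exact test), while against all annotated genes they passed in the other direction (odds ratio 2.77); adjusted p ranged from 0.000117 to 1 over their alternatives.

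Of 32 motifs, 25 passed (17 and 8). This became 6 (5 and 1) in the 1000 strongest peaks, with fewer windows, 12 (10 and 2) against candidates of the same GC content and 9 (6 and 3) in distal peaks; the less frequent ones fell to 4 in the 3512 peaks with the higher signal and to 4 within 50 bp. Directions reversed against candidates of the same GC content for Zelda (1.07) and nuclear receptor (1.08) sites, in distal peaks for the DRE (0.624), Motif 1 (0.333), TATA box (0.770), DPE (0.548) and Pho site (1.03), and in the 1000 strongest peaks for the DPE (0.580); none of these reversed values passed. The CTCF core was equally frequent in candidates of the same GC content (odds ratio 1). That setting also puts remaining candidates in place of flanks, so a changed value cannot be assigned to GC content alone. The 6-mers past the threshold were 538 (257 and 281) against candidates of the same GC content and 469 (240 and 229) in distal peaks, against 1057 (497 and 560), and the 10 named 6-mers stayed past it in all 4 alternatives. Arms with fewer peaks were 2 against base pairs and 1 to 2 without either replicate, with chromosome 4 added. The CG34376 locus exceeded 78.7% of windows with 50 kb on each side and 85.9% to 92.2% without either replicate.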

Other observations

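The lists of metabolic genes, the bases beside CTTATC, the motifs of ribosomal protein promoters, the sides of the summit and the test of extra copies of the CG34376 locus were chosen only after the result was seen. The nearest-start assignment was also chosen after the data were seen, but its prediction was written before its own result. The other tests of explanations were written before their results. Of the 32 motifs, 6 differed in frequency between peaks at cytosolic ribosomal protein promoters and peaks at other promoters. Of 98 such peaks, 19.4% held the DRE against 4.85% of 4204 other promoter peaks (adjusted p = 6.31e-06, Fisher's exact test) and 16.3% held the E-box CACGTG against 3.28% (adjusted p = 6.31e-06). The Pho site was in 41.8% against 27.5% (adjusted p = 0.0179, Fisher's exact test). The initiator TCAGTY was in 7.14% against 24.0% (adjusted p = 0.000324, Fisher's exact test), the GATA site in 23.5% against 41.01% (adjusted p = 0.00297) and the GAGA element in 1.02% against 8.21% (adjusted p = 0.0223). The base after CTTATC was C in 3.21% of 2240 matches at summits against 13.6% of 1662 in flanks (adjusted p = 2.56e-32, Fisher's exact test), while G (31.1% against 24.1%, adjusted p = 9.9e-06) and A (44.2% against 37.2%, adjusted p = 4.86e-05) were more frequent there. The base after that was T in 15.7% against 25.3% (adjusted p = 1.81e-12, Fisher's exact test).

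Since Gapdh2 and Hex-A were among the strongest peaks, 6 lists of metabolic genes were tested, and none passed. Glycolytic enzyme genes had 9 of 12 bound (75%, adjusted p = 0.249, Fisher's exact test), while mitochondrial complex I genes had 9 of 33 (27.3%, adjusted p = 0.131). The 9 bound glycolytic genes include Gapdh2 and Hex-A, the peaks that prompted the list. Their signals ranged from 164 at Tpi to 2799 at Gapdh2 with a median of 413, and were 1555 at Eno and 655 at Pgk. Cytochrome c oxidase genes and ATP synthase genes each had 6 of 11 bound, vacuolar ATPase genes 13 of 23 and N-linked glycosylation (Alg) genes 3 of 7. The share of ATP synthase genes depended on the library, 25% with replicate 2 alone and 72.7% with replicate 3 alone. By annotated biotype, 49.7% of 8426 protein-coding genes in the background were bound and 36.1% of 822 genes of the ncRNA class. The tRNA class had 71 of 197 bound (36.0%), pseudogenes 14 of 39 (35.9%), snoRNA genes 35 of 73 (47.9%) and snRNA genes 7 of 13 (53.8%). Differences between biotypes were not tested. From the fifth of the peaks with the highest signal to that with the lowest, the share with CTTATC was 25.6% (Wilson interval 23.4 to 28.0), 26.8%, 27.4%, 23.8% and 23.3% (21.2 to 25.6), with no steady trend. CTTATC lay 150 to 350 bp to the left of the summit alone in 914 thresholded peaks and to the right alone in 754 (exact binomial p = 9.78e-05), with 899 and 758 in replicate 2, 895 and 755 in replicate 3, and 2469 and 1903 in pooled candidates below the threshold (exact binomial p = 1.16e-17); for the scrambled TTCATC the numbers were 518 and 550 (exact binomial p = 0.343). The 22975 pooled candidates below the threshold include 2727 that overlap a thresholded peak. The thresholded and replicate lists also share most of their sites, so these counts are not independent of one another. Nearer the summit the shares of thresholded peaks with CTTATC per 50 bp ran slightly the other way. They were 7.42% at 50 bp to the left and 8.10% to the right, 6.12% and 6.56% at 100 bp, and 5.02% and 5.17% at 150 bp. These differences were not tested. Left and right are in genome coordinates, whatever the strand of a gene, so an offset in how the deposited summits were placed is not excluded, and the cause was not tested.

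CTTATC was more frequent at summits than in flanks. GC content was argued against, since the odds ratio was 2.00 (95% interval 1.84 to 2.18) against remaining candidates of the same GC content. Mean GC content differed little without matching, 41.8% in summit windows and 42.8% in remaining candidates. Other features of base composition were not matched, so they stay open. Promoter sequence in general was argued against as well, since the odds ratio among 2723 peaks over 500 bp from a start was 3.46 (3.09 to 3.87). The enrichment may reflect binding at such sites, as a hypothesis that these comparisons do not test. Whether CG34376 or a different protein contacts them stays open, as does signal common to many ChIP experiments. No biological explanation was tested, because the design has no other factor or untagged line to set beside it.

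Cytosolic ribosomal protein promoters were bound more often than others. More annotated starts per gene was argued against, since 0% of 10000 random lists matched on the number of starts reached 80 bound genes, where 43.8 were expected. Peaks of neighbouring genes were argued against, since with each peak given to the gene of its nearest start the odds ratio was 14.3 (adjusted p = 7.02e-19, Fisher's exact test). A signal that does not come through CTTATC stays open, and the prediction written beforehand for it was met. That prediction concerned CTTATC alone and not the other motifs more frequent at summits than in flanks. Among those, the DRE (19.4% against 4.85% of other promoter peaks) and the E-box CACGTG (16.3% against 3.28%) were more frequent in these peaks. The GATA site (23.5% against 41.01%), the initiator (7.14% against 24.0%) and the GAGA element (1.02% against 8.21%) were less frequent in them. CTTATC was no more frequent in these peaks than in their flanks, 5.10% against 7.14% (odds ratio 0.699, 95% interval 0.244 to 2.00, Fisher's exact p = 0.619). At other promoter peaks its odds ratio was 2.31 (2.08 to 2.56), and the difference itself was not tested. Signal common to many ChIP experiments at highly transcribed genes could give this, and no biological explanation was tested.

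The CG34376 locus held 10 thresholded summits, more than 90.1% of windows around other genes. Extra copies of the locus on the transgene could raise its signal, but candidates below the threshold there exceeded those of 61.2% of windows, between the 50% at which the explanation would have been set aside and the 95% it needed. Extra copies and binding at the gene's own locus therefore cannot be told apart, since the transgene's extent and a library without it are not analysed here, and no biological explanation was tested.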
